A study of Mus musculus with 14 samples.

How the data were processed

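Leukocytes that carry CD45 had been sorted by flow cytometry from needle biopsies of the livers of untreated wild-type mice, per the labels, at 2500, 5000, 10000 or 20000 cells per sample. Total RNA was isolated with a column kit and DNase, and cDNA was made with the SMART-seq v4 ultra-low-input method and tagmented into libraries, per the labels' protocols. Each cell number had 3 libraries and bulk liver had 2, so that 14 libraries were used, and 0 columns of per-sample values were left unmapped.

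The authors deposited 3 tables over 48794 genes, with 1 column per sample and no pooling. The deposited count table holds raw counts per gene as whole numbers. The deposited TPM table holds TPM values, in which each column sums to the same total. Some genes have counts but a TPM of 0, and the reverse, so the TPM were not made from the deposited counts alone. The third deposited table holds a score per gene, a variance-stabilised value that rises strictly with the counts within a column. Per the submitters' processing notes, STAR 2.5.2b, RSEM 1.3.0, featureCounts 1.5.1, FastQC 0.11.5 and DESeq2 1.34.0 were used with the genome build GRCm38. The notes give no role or order of these tools, and no annotation release, filter or strand setting. The comparisons rest on the counts, and the TPM and the scores were used only in alternatives. Gene IDs were matched to symbols for 48348 genes, 446 had none, and 126 IDs share a symbol with another ID. Coordinates on GRCm38 come from GENCODE M21 for 48434 genes.

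Total counts per library ranged from 6723357 to 14496314. A gene with no count in a group was compared with a floor of 3 counts over the group, which is 0.393 CPM over both bulk libraries, and its fold is given as a lower bound. With 1 to 3 counts the ratio is given with its 95% counting interval. Medians of lists are also given with such genes at their bound. CPM (counts scaled to library size) of single genes were scaled with TMM (trimmed mean of M values) factors within the fit they belong to, while shares of counts and the plots by input use library totals.

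Genes were tested with the edgeR quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3; robust fit, TMM factors, filterByExpr by group), and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit of sorted cells against bulk liver held all 14 libraries with a mean per group, and its contrast set the mean of the 4 sorted groups against bulk. The fits on input held the 12 sorted libraries. They tested the slope on the log2 of the cell number, any difference between the 4 inputs, and each of the 3 lower inputs against 20000 cells. Replicate numbers were not used as pairs, since the labels do not say that equal numbers mark one animal.

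In all, 34 gene lists with 457 members were written down, of which 456 members were matched, 1 of them by a synonym. They cover leukocytes in general, Kupffer cells, monocytes, neutrophils, dendritic cells, T cells, natural killer and innate lymphoid cells, B cells, plasma cells, mast cells and basophils, hepatocytes, sinusoidal endothelium, stellate cells and fibroblasts, cholangiocytes, erythroid cells, platelets, coagulation and plasma proteins, complement, the urea cycle, bile acids, cytochrome P450, gluconeogenesis, MHC class II, cytokines, Toll-like receptors and inflammasomes, interferon-stimulated genes, T cell inhibitory receptors, proliferation, immediate early genes, heat shock, mitochondrially encoded genes, ribosomal proteins, nuclear-retained transcripts and Y-linked genes. Lists with at least 3 tested members were compared with the other genes by camera with a preset correlation of 0.01 (limma 3.58.1), adjusted over the lists, and again with an estimated correlation. The fry test asked whether the members of a list move one way on balance. The same list tests between 2500 and 20000 cells were added after the values were seen.

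The comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. For sorted cells against bulk liver the rule named Ptprc, then the 10 genes with the highest and the 10 with the lowest log2 fold change among those that passed, had at least 50 CPM in bulk or sorted samples and did not overlap between them. It also named the 2 members of each list with the highest mean CPM. For the input comparisons it named up to 10 genes per direction with the smallest p among those that passed with at least 5 CPM, and the same list members. Gene models known only by a number, clones and pseudogenes were counted and not named. Genes given as further examples of list members were chosen after their values were seen.

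For the number of detected genes each library was thinned at random, with a fixed seed, to 6723357 counts. That number and the hepatocyte share of counts were related to the log2 of the cell number by Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples. Replicate spread was the median over 9649 genes with a mean of at least 10 CPM of the SD of log2(CPM + 1). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps.

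The tests were run on simulated counts with the totals of the real libraries and a single mean per gene over the libraries of a fit. In them 100 genes were changed 2-fold and 100 genes 4-fold, drawn from genes above a minimum of expected counts. For sorted cells against bulk liver 74% and 93% of them were recovered, with 11 false calls among 15999 genes. In the real comparison 80.3% of genes were called, so most genes differed. The simulation did not reproduce this, and its rates do not carry over to that comparison. For 2500 against 20000 cells 77% and 98% were recovered, with 14 false calls among 14604. For 5000 cells these were 84% and 97%, with 2 among 14589, and for 10000 cells 78% and 97%, with 9 among 14583. For any difference between inputs they were 84% and 98%, with 13 among 14557. For the slope, changes of 0.33 and 0.66 on the log2 scale per doubling were recovered in 79% and 98% of genes, with 12 false calls among 14587. Camera called 2 of 2 shifted lists and 1 of 31 unshifted ones.

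The alternatives were median-of-ratios size factors, library totals, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 5 CPM, libraries thinned to equal totals, a fold change of at least 2 as well, a replicate block, bulk libraries in the input fits, the hepatocyte share as a covariate, immunoglobulin and T cell receptor segments left out (699 genes), each sorted group alone against bulk, the sorted libraries as 1 group, and each library left out in turn. For the measures per library they were other count minimums, TPM, pseudocounts and the deposited scores. Sequence reads, GC content and gene length were not analysed here.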

Results

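RNA was sequenced from the livers of untreated wild-type mice in 14 libraries. For 12 of them the RNA came from leukocytes that carried CD45, a surface phosphatase of nucleated blood cells, and that flow cytometry had sorted out of needle biopsies. The sorted samples held 2500, 5000, 10000 or 20000 cells, with 3 libraries at each number. The other 2 libraries were made from bulk liver tissue, which the series names as the control. Total counts were 7605290 and 8034138 in the bulk libraries and ranged from 6723357 to 14496314 in the sorted ones, over 48794 annotated genes of the mouse genome build GRCm38. Across genes, which are not independent replicates, the Spearman correlation of counts was 0.994 between the bulk libraries, 0.973 to 0.993 between sorted libraries of the same cell number, and 0.396 to 0.415 between a sorted and a bulk library. The spread between libraries of a group was above sampling noise in every pair, since the chi-square statistic per degree of freedom was 1.59 for the bulk pair and 2.52 to 18.2 for the sorted pairs. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Intervals and lower bounds cover counting error only. The strand setting of the counting is not given in the sources used here, so antisense and overlapping genes are uncertain, as are near-identical copies such as Hba-a1 and Hba-a2, Mup20, Serpina1a, C4b, the Cyp2c and Cyp2d families and ribosomal protein genes with pseudogenes.

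The first comparison set the sorted cells against bulk liver and shows which transcripts were higher or lower in sorted cells. Handling differs between them too, so the differences cannot be credited to sorting for CD45 alone. Ptprc, the gene that encodes CD45 (ENSMUSG00000026395, chromosome 1, 138062861 to 138175708, minus strand), stood at 2249 ± 67.6 CPM (SD, n = 12) in sorted cells and 21.3 ± 5.45 CPM (SD, n = 2) in bulk liver. Its log2 fold change was 6.72 (SE 0.11; adjusted p = 2.1e-21, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and all 12 sorted libraries lay above both bulk libraries. Alb, which encodes the plasma protein albumin made by hepatocytes (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602, plus strand), went the other way, from 42975 ± 1126 CPM in bulk liver to 43.2 ± 7.48 CPM in sorted cells (log2 fold change -9.97, SE 0.10; adjusted p = 8.4e-21, same test). The 26 hepatocyte genes fixed as a list took 14.0 ± 0.0814% of bulk counts and 0.0581 ± 0.00664% of sorted counts.

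Of 16294 genes tested, 6806 were higher and 6273 lower in sorted cells, together 80.3%. At least 10-fold differences numbered 2114 upward and 2111 downward. These directions are relative to the other genes. When libraries were scaled by their totals alone, which moved the median of all genes from 0.17 to 1.37, 10738 genes were higher and 3654 lower, so that the share of higher calls was 74.6% against 52.0%.

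Among abundant genes with the largest rise were Prf1, the pore-forming perforin of cytotoxic lymphocytes, and Runx3, a transcription factor of the same cells. Neither had a count in the bulk libraries. Prf1 (chromosome 10, 61297833 to 61304680) reached 163 ± 17.9 CPM in sorted cells, at least 415-fold higher against a floor of 3 counts over both bulk libraries. Runx3 was at least 166-fold higher, Scml4 at least 209-fold, Gpr174 at least 182-fold, Chst3 at least 172-fold and Hsh2d at least 140-fold. The monocyte genes Chil3 and F13a1 had 1 and 2 counts in bulk liver. Their ratios were 2219 (95% counting interval 398 to 87649) and 1699 (470 to 14032). B3gnt5 and Skap1, each with 1 bulk count, gave ratios of 1489 (267 to 58803) and 1165 (209 to 45999).

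Among the genes with the largest fall were Abcb11 and Cyp7a1, which act in bile formation. Abcb11, the bile salt export pump, dropped from 730 ± 30.8 CPM in bulk liver to 0.235 ± 0.281 CPM (log2 fold change -13.17, SE 0.12; adjusted p = 4.4e-21, edgeR). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 3 counts over all 12 sorted libraries against 104 ± 4.16 CPM in bulk liver, and Abcg5, part of a sterol transporter, had 1 count against 94.02 ± 0.781 CPM. The ratios of bulk liver to sorted cells were 4449 (95% counting interval 1522 to 21574) for Cyp7a1 and 12076 (2167 to 476976) for Abcg5. Nat8f5 had none and was at least 3021-fold lower. Nlrp6, with 3 sorted counts, and Serpina7, with 2, had ratios of 8643 (2958 to 41912) and 6248 (1730 to 51596). Prodh2, Uroc1, BC024386 and BC025446 were the other genes of this group.

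Most lists of leukocyte genes rose. All 15 members of the pan-leukocyte list passed upward, with a median log2 fold change of 5.55 (camera adjusted p = 2.8e-21). For example, Coro1a, an actin regulator, reached 2342 ± 121 CPM against 13.1 ± 0.407 CPM. All 13 monocyte genes rose (adjusted p = 8.9e-11), including Lyz2, which encodes lysozyme (8534 ± 496 against 303 ± 8.73 CPM), and Ccr2, a chemokine receptor (659.1 ± 24.5 against 3.40 ± 0.265 CPM). All 15 B cell genes rose (adjusted p = 4.0e-18), with Ighm at 3299 ± 312 CPM, as did all 15 T cell genes (adjusted p = 1.5e-09), with the kinase Lck at 392 ± 26.9 CPM. All 11 genes of antigen presentation by MHC class II rose (adjusted p = 1.9e-13). Cd74, the invariant chain, reached 9832 ± 689 CPM against 195 ± 5.79 CPM. All 15 genes of the Toll-like receptor and inflammasome list also rose (adjusted p = 7.0e-04), with Tlr13 at 140 ± 9.09 CPM against 2.74 ± 0.470 CPM. These 6 lists were also called with an estimated correlation between genes.

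For 4 further leukocyte lists the call was lost when the correlation was estimated. All 15 genes of natural killer cells and innate lymphoid cells rose (camera adjusted p = 3.1e-09, and adjusted p = 0.0838 with an estimated correlation), with Nkg7 at 382 ± 29.6 CPM and Gzma, a granule protease, at 371 ± 37.2 CPM. Of 13 dendritic cell genes 11 rose, among them Ccr7 (448 ± 26.5 CPM), Itgax and Siglech, and 2 did not pass (adjusted p = 0.0621 with an estimated correlation). Of 14 neutrophil genes 9 rose, including S100a8 and S100a9, and G0s2, an inhibitor of lipolysis, fell (log2 fold change -2.73). Adjusted p for that list was 0.00713, and adjusted p = 0.276 with an estimated correlation. All 10 genes of the T cell inhibitory receptor list, not all of which encode receptors, rose, such as Cd244a and Entpd1 (adjusted p = 0.0719 with an estimated correlation). The medians of these 4 lists were 8.22, 7.02, 7.44 and 5.01, and with genes absent from bulk liver set at their bound 8.17, 6.39, 6.79 and 3.56.

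Lists of parenchymal function fell without exception. All 26 hepatocyte genes passed downward, with a median of -9.91 (camera adjusted p = 4.9e-79). So did all 15 genes of coagulation and plasma proteins (median -8.95), all 15 of complement (-9.03), all 7 of the urea cycle (-9.50), all 11 of bile acid synthesis and transport (-9.86), all 13 tested cytochrome P450 genes (-10.80) and all 9 of gluconeogenesis and glycogen metabolism (-10.15). The complement factor C3, for example, stood at 117 ± 16.2 CPM in sorted cells and 6568 ± 573 CPM in bulk liver. These 7 lists were called with either correlation setting. Of 16 genes of stellate cells and fibroblasts 15 fell, including the collagen genes Col1a1 and Col1a2 (camera adjusted p = 0.0234, and adjusted p = 0.0563 with an estimated correlation).

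Kupffer cell genes, which mark the resident macrophages of the liver and carry CD45, did not move with most of the other leukocyte lists. Of 14 members 12 were lower in sorted cells and 2 higher, with a median log2 fold change of -0.88 (camera adjusted p = 0.827). Clec4f, a lectin of Kupffer cells (chromosome 6, 83644542 to 83656187), stood at 148 ± 30.4 CPM in sorted cells and 283 ± 40.8 CPM in bulk liver (adjusted p = 2.3e-05, edgeR), and Slc40a1, the iron exporter ferroportin, at 212 ± 35.2 against 449 ± 30.9 CPM (adjusted p = 9.7e-09). Cd68 (log2 fold change 2.68) and Adgre1 (0.60) were the members that rose. With scaling by library totals the list's median was 0.33, 7 members were higher and none was lower, and the estimates for Clec4f and Slc40a1 changed sign to 0.26 and 0.12, neither of which passed.

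Other cell types gave mixed lists that were not called. Of 16 sinusoidal endothelial genes 15 fell, such as Stab2 (-2.83) and Lyve1 (-3.66), and Pecam1, an adhesion molecule that leukocytes also carry, rose (1.89; list adjusted p = 0.109). Of 8 tested cholangiocyte genes 6 fell, including Sox9 and Spp1 (adjusted p = 0.392). All 6 erythroid genes fell (adjusted p = 0.495), from 316 ± 19.3 to 2.64 ± 1.57 CPM for Alas2, the heme synthesis enzyme of red cell precursors. Of 6 platelet genes 3 rose, and Pf4 did not pass (adjusted p = 0.549 for the list). Of 7 plasma cell genes 4 rose, among them Igha, the constant region of immunoglobulin A (151 ± 96.2 against 3.66 ± 0.627 CPM, but not passing for 2500 cells alone against bulk liver), and 2 fell, including the proteoglycan gene Sdc1 (adjusted p = 0.549). The mast cell and basophil list had only 2 tested members and no list test, with Hdc higher (31.4 against 8.42 CPM) and Gata2 lower (0.346 against 3.65 CPM).

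Among lists of cell state, all 16 immediate early genes that tissue dissociation is known to induce were higher in sorted cells (median 2.74, and 2.62 with bounds; camera adjusted p = 3.1e-06, and adjusted p = 0.0268 with an estimated correlation). Fos and Nr4a1, for example, rose by 7.28 (SE 0.23) and 6.97 (SE 0.20) on the log2 scale, and Egr1 by 0.71. Handling and cell type both differ between sorted cells and bulk tissue, so their parts in this rise cannot be told apart. Of 11 heat shock genes 9 fell, such as Hspd1 (-3.11), and Hspa1a and Dnajb1 rose (adjusted p = 0.0290, and adjusted p = 0.0853 with an estimated correlation). The cytokine and chemokine list had 9 members higher, including Il1b (5.75), Ccl3 and Ccl4, and 5 lower, including Cxcl1 (-8.50) and Il18 (adjusted p = 0.0966). The interferon-stimulated list likewise had 9 members higher, such as Mx1, and 5 lower, such as Isg15 (adjusted p = 0.245). Of 15 proliferation genes 13 rose, including Mki67 and Top2a (adjusted p = 0.111). All 8 tested mitochondrially encoded genes were lower (adjusted p = 0.223), as were Malat1 and Neat1 of 3 nuclear-retained transcripts (adjusted p = 0.212). The 30 ribosomal protein genes went both ways, 8 higher and 11 lower (adjusted p = 0.628; the median was -0.11 while the test pointed upward), and 3 of 4 Y-linked genes were higher (adjusted p = 0.538). Under library totals these lists changed direction in part, with 13 cytokine genes higher and 1 lower, 14 interferon-stimulated genes higher and 1 lower, 30 ribosomal protein genes higher, Malat1 higher at 0.38, and 4 mitochondrial genes still lower. In all, 33 of the 34 lists were tested and 20 called, 14 of them also with an estimated correlation. Of 427 tested members 200 rose and 193 fell, both over all genes and adjusted over the list alone.

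**Figure D1:**
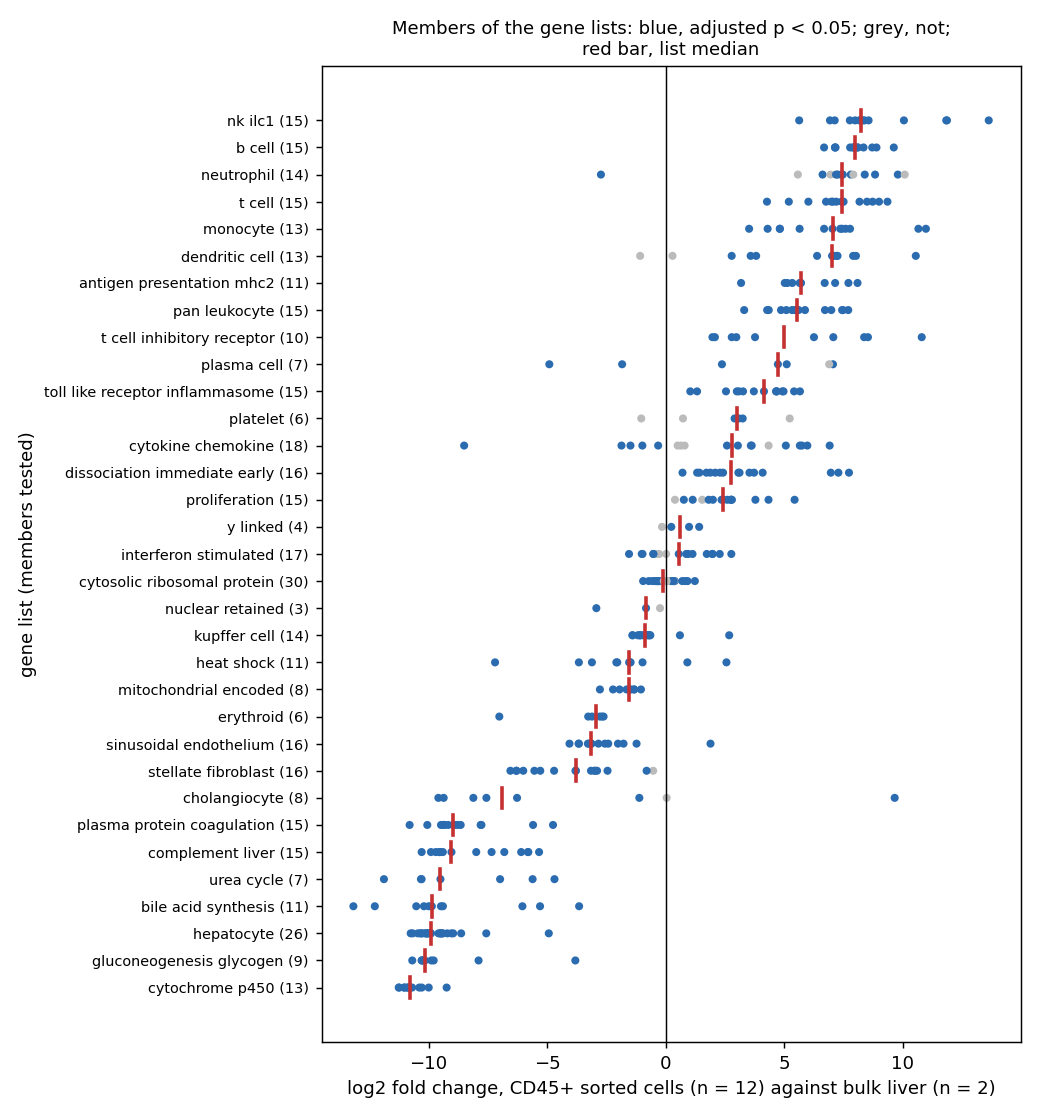
Log2 fold change of CD45+ sorted cells (n = 12) against bulk liver (n = 2) on the horizontal axis for each tested member of the 33 gene lists, listed on the vertical axis with the number of members tested. Points are genes, blue where the adjusted p was under 0.05 and grey otherwise, and red bars are list medians, which run from -10.80 for cytochrome P450 genes to 8.22 for natural killer cell genes.

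The second comparison asked how the profile depends on the number of sorted cells. The clearest differences were in the counts of single genes at either end of the range. Jchain, which encodes the joining chain of secreted immunoglobulin A and M (ENSMUSG00000067149, chromosome 5, 88519809 to 88527891, minus strand), stood at 0.352 ± 0.3303 CPM (SD, n = 3) at 2500 cells and 58.0 ± 1.27 CPM (n = 3) at 20000 cells, with a log2 difference of -7.28 (SE 0.53; adjusted p = 1.5e-04, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Igha went with it, at 13.4 ± 13.2 against 240 ± 52.0 CPM (log2 difference -4.13, SE 0.63; adjusted p = 0.0456), a call that was lost in 10 of 12 repeats that left out 1 library, with adjusted p of 0.0908 and 0.0683 without 2500-cell replicates 1 and 3, 0.0825 and 0.0578 without 5000-cell replicates 1 and 2, 0.0718, 0.0828 and 0.0746 without 10000-cell replicates 1, 2 and 3, and 0.0961, 0.138 and 0.185 without 20000-cell replicates 1, 2 and 3. Lars2, the mitochondrial leucyl-tRNA synthetase gene (ENSMUSG00000035202, chromosome 9, 123366927 to 123462666, plus strand), was highest at 20000 cells, at 4425 ± 510 CPM against 1486 ± 59.3 at 2500, 1468 ± 135 at 5000 and 2032 ± 106 at 10000 cells. Mir6236, a microRNA gene model (chromosome 9, 110281287 to 110281409), was also highest at 20000 cells, at 693 ± 39.3 CPM against 263 ± 14.0 at 2500, 236 ± 19.9 at 5000 and 260 ± 43.7 at 10000 cells. Markers of the sort did not differ by a test between 2500 and 20000 cells, with Ptprc at a log2 difference of 0.05 (SE 0.04) and Coro1a at 0.11 (SE 0.05).

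Between 2500 and 20000 cells, 62 of 14795 genes differed, 50 of them lower at 2500 cells and 12 higher. After Lars2, Mir6236 and Jchain, the lower genes with the smallest p were the RNA-binding protein gene Qk (chromosome 17, 10202601 to 10319854), at 72.8 ± 7.35 against 157 ± 22.5 CPM (log2 difference -1.11, SE 0.13; adjusted p = 3.2e-04, edgeR), then Kctd12 (-0.91), Tada2b (-1.40), Znrf2 (-1.22), Fam120a (-0.66), Heca and Purb (-0.88). Higher at 2500 cells were the Kupffer cell genes C1qa, a subunit of the complement starter C1q (64.8 ± 8.80 against 42.1 ± 1.09 CPM; log2 difference 0.62, SE 0.12; adjusted p = 0.0285), and Cd5l, a secreted macrophage protein (117 ± 16.8 against 73.3 ± 7.68 CPM; 0.67, SE 0.14; adjusted p = 0.0436). The lymphocyte genes Dgka (0.30), Cd6 (0.44) and S1pr1 (0.22), the selectin ligand gene Selplg (0.25), and Cd2bp2, Uba7, Taf8 and Faah were also higher. Of the 21 named genes that passed here, 14 lost the call or changed sign in at least 1 alternative. This count includes a contrast of 2500 cells with the mean of 5000 and 10000 cells, chosen after seeing the data. That contrast leaves out 20000 cells and so is another comparison, in which 13 calls ended and Mir6236 changed sign. With the hepatocyte share as a covariate 11 of the 21 calls ended. The call of C1qa ended with limma-voom (adjusted p = 0.0536), with the hepatocyte share as a covariate (0.106, at a log2 difference of 0.56), and without 2500-cell replicate 3 (0.0683) or 20000-cell replicates 1, 2 or 3 (0.0707, 0.138 and 0.124). That of Cd5l ended with limma-voom (adjusted p = 0.0632), with the covariate (0.132, at 0.53), with bulk libraries in the fit (0.0872, at 0.66), and without 2500-cell replicates 2 or 3 (0.0913 and 0.0649), 5000-cell replicate 3 (0.0600), 10000-cell replicate 3 (0.0567) or 20000-cell replicates 1, 2 or 3 (0.0923, 0.129 and 0.235). Leaving out single libraries ended the call for S1pr1 in 12 of 12 cases, for Cd6, Selplg, Uba7, Taf8 and Faah in 11, for Dgka in 10 and for Cd2bp2 in 5. The count fell to 39 without 2500-cell replicate 2, to 38 without 5000-cell replicate 1, to 36 and 35 without 10000-cell replicates 2 and 3, and to 36, 19 and 22 without 20000-cell replicates 1, 2 and 3. Limma-voom called 23 genes, 1 higher and 22 lower, and DESeq2 called 267. All 10 named genes that were higher at 2500 cells lost their call with limma-voom and with the hepatocyte share as a covariate.

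Between 5000 and 20000 cells 13 genes differed, all of them lower at 5000 cells. With Lars2 (log2 difference -1.59, SE 0.08; adjusted p = 4.6e-09, edgeR) and Mir6236 (-1.56, SE 0.10) they included Max, the dimer partner of the Myc transcription factors (16.9 ± 3.83 against 48.9 ± 9.52 CPM; adjusted p = 0.0037), Tmbim6 (-0.50), Bahd1, Stk24 (-0.66), Paip2b (-1.02), Elf2 (-0.49), Itpkb (-0.72) and the lymphoid transcription factor gene Ikzf1 (-0.39; adjusted p = 0.0406). With the hepatocyte share as a covariate 8 of the 10 named calls ended, while all 8 kept their direction, for example at -0.90 for Bahd1, -0.55 for Stk24, -0.34 for Ikzf1 and -1.07 for Max. Leaving out single libraries ended the call for Itpkb in 8 of 12 cases, for Ikzf1 in 7, for Stk24, Paip2b and Elf2 in 5 and for Bahd1 in 4. No gene passed upward, although 499 were higher at an unadjusted p under 0.05, and limma-voom called 0 genes higher and DESeq2 9. The count was 24 without 2500-cell replicate 3, 7 and 6 without 5000-cell replicates 1 and 3, 7 without 10000-cell replicate 2, and 29, 7 and 6 without 20000-cell replicates 1, 2 and 3.

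Between 10000 and 20000 cells 45 genes differed, 43 of them lower at 10000 cells. Lars2 (-1.12, SE 0.08; adjusted p = 9.0e-07, edgeR) and Mir6236 (-1.41, SE 0.10) were again among them, with Max (-1.49), Kctd12 (-0.90), Kdelr1 (-0.81), Laptm4a (-0.52), Rap1a (-0.52), Ptma (-0.50), the ribosomal protein gene Rps24 (-0.52) and the monocyte gene Ly6c2 (403 ± 8.07 against 534 ± 47.3 CPM; -0.41, SE 0.06; adjusted p = 0.0045). The 2 higher genes were the macrophage genes C1qc (107 ± 19.7 against 66.9 ± 4.95 CPM; 0.67, SE 0.12; adjusted p = 0.0315) and Nrros (0.27, SE 0.05; adjusted p = 0.0439). The call of C1qc was lost with the hepatocyte share as a covariate (adjusted p = 0.104, at a log2 difference of 0.63), and without 10000-cell replicates 1 or 2 (adjusted p of 0.0665 and 0.138) or 20000-cell replicates 1, 2 or 3 (0.0749, 0.0766 and 0.190). The call of Nrros was lost with the covariate (adjusted p = 0.126, at 0.25), with bulk libraries in the fit (0.0924, at 0.26), and without 2500-cell replicate 1 (0.0506), 5000-cell replicate 2 (0.0590), 10000-cell replicates 1, 2 or 3 (0.132, 0.138 and 0.214) or 20000-cell replicates 1, 2 or 3 (0.0799, 0.157 and 0.232). Rap1a, Kdelr1, Ptma and Rps24 lost theirs in 3 of 12 such repeats and Laptm4a in 1. The count was 21 with scaling by library totals. It was 114 without 2500-cell replicate 3, 10, 13 and 9 without 10000-cell replicates 1, 2 and 3, and 13 and 7 without 20000-cell replicates 2 and 3. DESeq2 called 89 genes for 5000 cells and 197 for 10000 cells.

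The slope on the log2 of the cell number does not ask whether a change was steady at each doubling. Over the whole range it passed for 12 genes, 9 of them upward. Named among these were Purb, a single-stranded nucleic acid binding protein gene, which rose by 0.30 on the log2 scale per doubling of cells (SE 0.05; adjusted p = 0.0232, edgeR), Tada2b, a subunit of a histone acetyltransferase complex, by 0.50 (SE 0.08), Fam120a by 0.24 (SE 0.04), Rab21 by 0.19, Ppp2cb by 0.24, Zswim6 by 0.35 and Csnk2a2 by 0.24. Purb went from 37.6 ± 4.51 CPM at 2500 cells through 51.8 ± 10.3 and 65.7 ± 7.97 to 69.4 ± 4.24 CPM at 20000 cells. Lars2 had a slope of 0.52 (SE 0.08) that did not pass (adjusted p = 0.0577). At an unadjusted p under 0.05 there were 1580 genes where 739.8 would be given by chance, and DESeq2 called 127. The slope count fell whichever library was left out. It was 0 without 2500-cell replicate 2 or 3 or without 20000-cell replicate 1 or 2. In these 4 repeats 1673, 1621, 1289 and 1360 genes had an unadjusted p under 0.05. Leaving out 5000-cell replicates 1 and 2 and 10000-cell replicates 1, 2 and 3 in turn gave 4, 5, 5, 3 and 6 genes, and the 3 remaining libraries gave 8, 8 and 10. In repeats chosen after seeing the data, 15 genes passed without the whole 2500-cell group, none of them among the 7 named genes, and 13 without the 20000-cell group, where 4 of the 7 named calls ended. With the hepatocyte share as a covariate 6 genes passed and 4 of the 7 named calls ended. A test for any difference between the 4 inputs called 44 genes by edgeR and 309 by DESeq2. That count was 71, 69 and 104 without 2500-cell replicates 1, 2 and 3, 28 without 5000-cell replicate 1, 24, 23 and 26 without 10000-cell replicates 1, 2 and 3, and 20 without either 20000-cell replicate 2 or 3.

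**Figure D2:**
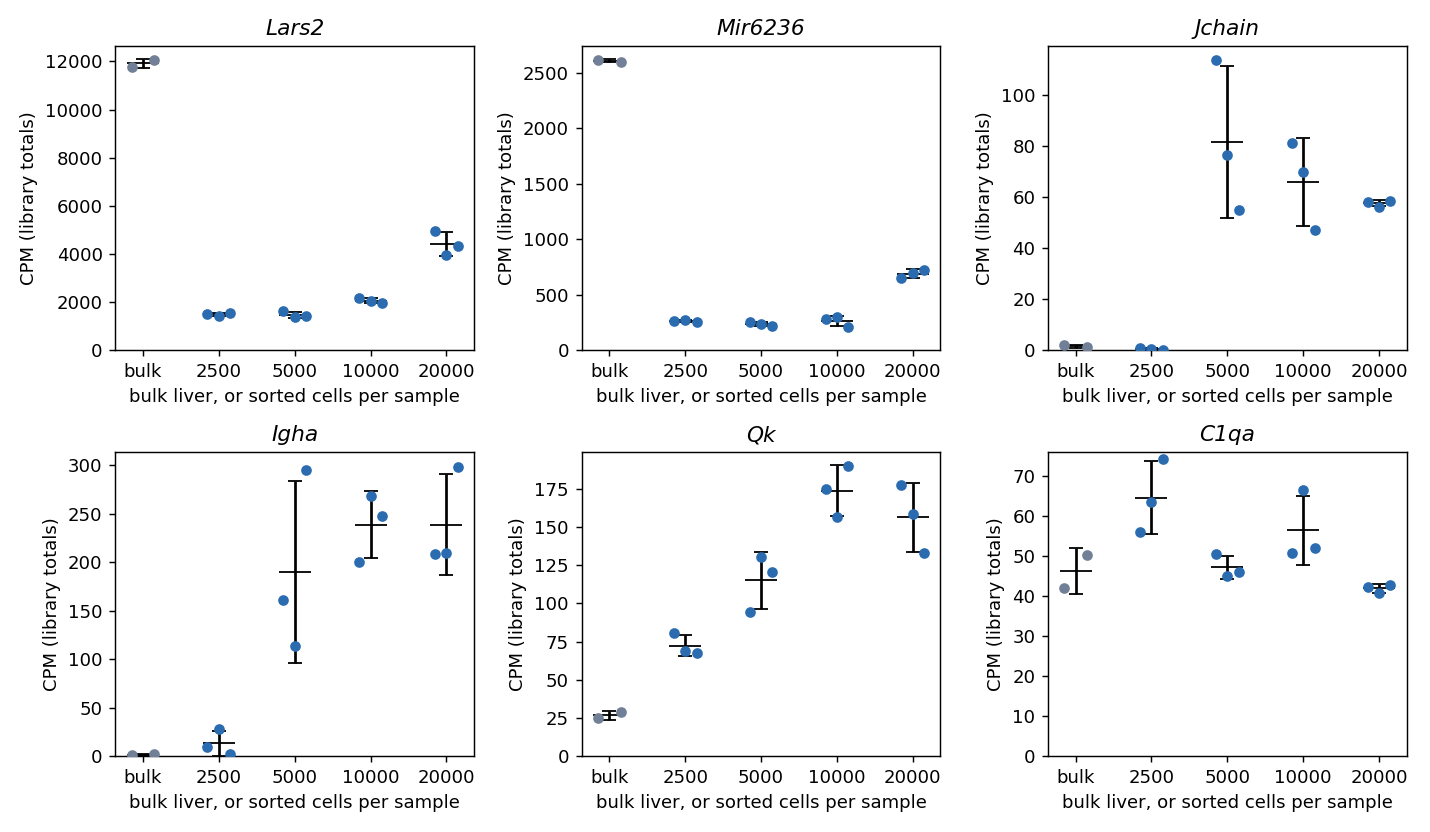
CPM on library totals (vertical axes, starting at 0) in each library of bulk liver and of sorted cells at the 4 cell numbers (horizontal axes) for 6 named genes, with points for libraries and dashes with error bars for group means and SD. Jchain lies at 0 to 0.65 CPM in the 3 libraries of 2500 cells and at 47.1 to 114 CPM in the 9 libraries of more cells.

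On the slope, camera with its preset correlation called 10 of 33 lists. Those of plasma cells (median 0.31 on the log2 scale per doubling), erythroid cells (0.44), monocytes (0.04) and proliferation (0.09) pointed upward, and those of Kupffer cells (-0.09), B cells (-0.02), hepatocytes (-0.09), bile acid synthesis (-0.11), gluconeogenesis (-0.17) and mitochondrially encoded genes (-0.15) pointed downward. All 10 calls were lost with an estimated correlation, for which adjusted p = 0.407 was the lowest of the 33 lists and 3 lists had an unadjusted p under 0.05. The fry test called 0 lists (lowest adjusted p = 0.135), with 6 at an unadjusted p under 0.05. Over all genes 0 of 400 tested members passed, and adjusted over the list alone 8 rose and 8 fell, 3 of the latter in the Kupffer cell list. For the lists of all leukocytes, neutrophils, interferon-stimulated genes and immediate early genes, none of them called, the median, the mean and the test differed in sign. List tests between 2500 and 20000 cells were added after the values were seen. There camera called 6 lists, of which the plasma cell list (median -1.15; camera adjusted p = 4.0e-16) was the only one called with an estimated correlation (adjusted p = 0.000786). It was lower at 2500 cells, with 2 of 7 members passing over all genes and 3 adjusted over the list alone. The members that passed over all genes were Jchain and Igha, so the list test in part restates them. Sdc1 hardly differed (16.95 against 17.26 CPM on library totals) and Prdm1 was not lower (32.88 against 29.22), while the other members were lower. Fry called the plasma cell list (adjusted p = 0.000242) and the monocyte list (median -0.18; adjusted p = 0.0265 by fry, and adjusted p = 0.185 with an estimated correlation).

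At equal depth the number of detected genes increased with the number of cells. With each library thinned to 6723357 counts, genes with at least 1 count numbered 19281 ± 316 at 2500 cells, 19580 ± 38.2 at 5000, 19658 ± 155 at 10000 and 19983 ± 80.3 at 20000 cells (SD, n = 3 each). That is 218 genes per doubling, with a Pearson r of 0.841 over 12 libraries (permutation p = 0.00047, adjusted 0.00094 over 2 relations) and a Spearman rho of 0.734 (permutation p = 0.0099, adjusted 0.0198). In all, 6 libraries tie as farthest from the median cell number. Leaving out any 2 of them gave r between 0.751 and 0.926. The relation was not found for genes with at least 5 counts (r = 0.194, p = 0.548 by permutation), for libraries that were not thinned (r = 0.372, p = 0.234 by permutation) or for genes above 1 TPM (r = 0.255, p = 0.425 by permutation).

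The hepatocyte share of counts, meant to measure transcripts from outside the CD45 gate, did not follow the cell number by these tests. It was 0.0579 ± 0.00598% at 2500 cells, 0.0648 ± 0.00534% at 5000, 0.0575 ± 0.00627% at 10000 and 0.0521 ± 0.00403% at 20000 cells, with r = -0.434 (permutation p = 0.157) and rho = -0.518 (permutation p = 0.0927). Leaving out 2 of the libraries tied as farthest gave r between -0.743 and -0.135. Without 2500-cell replicate 1 r was -0.633 (permutation p = 0.0372). The list member Hp had more counts than Alb in every sorted library, for example 1464 against 337 in 2500-cell replicate 1. In bulk liver replicate 1 it had 17954 against 157483. The share may therefore not measure only transcripts from outside the gate, and a share without Hp was not tried.

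Replicates differed most at the lowest input. The median over 9649 genes of the SD of log2(CPM + 1) between 3 libraries was 0.142 at 2500 cells, 0.107 at 5000, 0.0998 at 10000 and 0.0996 at 20000 cells. These are single values per group and were not tested. Without 20000-cell replicate 1 the value at 20000 cells was 0.0628, which rests on a pair of libraries and is not directly comparable with those over 3. The common biological coefficient of variation fitted within each group over the same genes was 0.135, 0.0947, 0.0805 and 0.0720 in the same order, and 0.0255 for bulk liver.

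**Figure D3:**
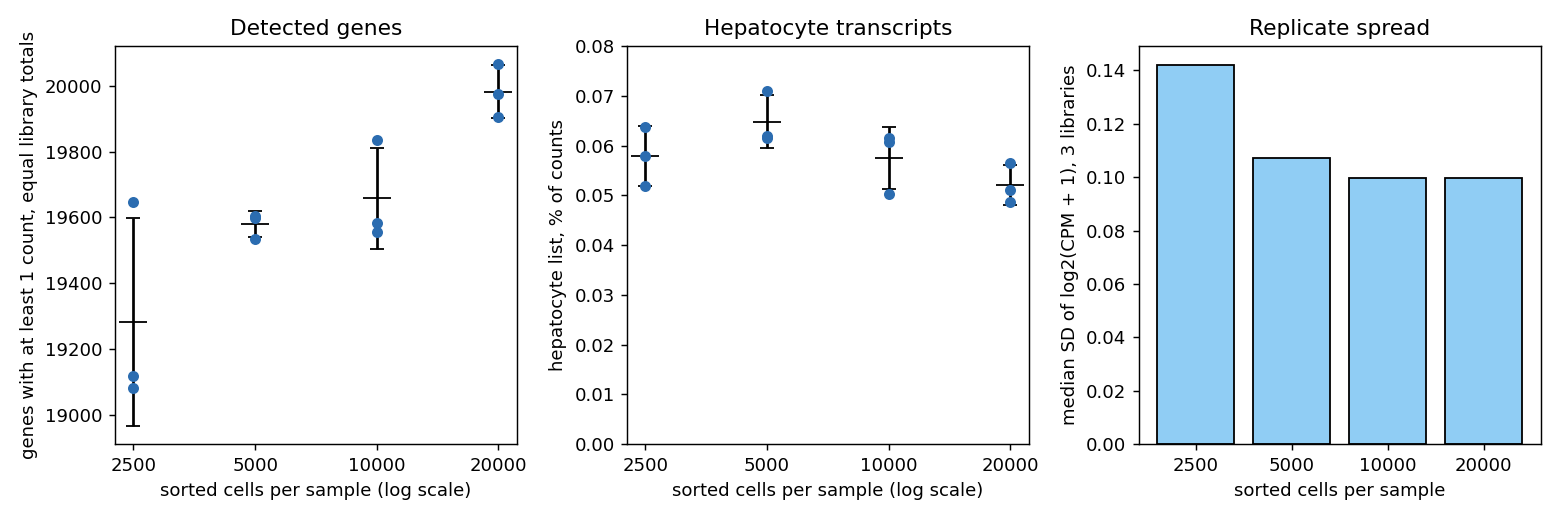
Detected genes at equal depth, hepatocyte share of counts in percent and replicate spread against the number of sorted cells per sample (log scale in the first and second panels). Points are libraries, and dashes with error bars are group means and SD. Bars in the third panel are the median SD of log2(CPM + 1), which is 0.142 at 2500 cells and 0.0996 at 20000 cells. Without 20000-cell replicate 1 it is 0.0628, over a pair of libraries and so not directly comparable.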

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

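The slopes without the 20000-cell or the 2500-cell group and the contrast of 2500 cells with the mean of 5000 and 10000 cells were chosen after seeing the data, and the cause was not tested where none is given. With library totals, 10738 genes were higher and 3654 lower in sorted cells, and 21 differed between 10000 and 20000 cells. The sign changed for Slc40a1 (0.12), Clec4f (0.26), Ccl9 (0.89), Hspa8 (0.23), Rplp0 (0.83), Malat1 (0.38) and Eif2s3y (1.05), since that scaling moves all genes. DESeq2 called 127 genes on the slope, 309 for any difference, and 267, 89 and 197 for 2500, 5000 and 10000 against 20000 cells. Limma-voom called 23 for 2500 cells. Without a filter the counts were 19, 605, 397, 203 and 286 in that order, and with a fold change of at least 2 as well 7, 18, 20, 7 and 8, as the stricter criterion requires. Bulk libraries in the fit gave 23 for the slope, 85 for any difference and 26 for 5000 cells. With the hepatocyte share as a covariate the counts were 6 for the slope, 20 for any difference, 17 for 2500 cells and 4 for 5000 cells. A replicate block gave 0 on the slope by edgeR, with 1585 at an unadjusted p under 0.05, where DESeq2 without the block gave 127 and limma-voom 15, and 7 of 12 libraries correlated best with their own replicate number. The contrast of 2500 cells with the mean of 5000 and 10000 cells gave 24 genes, and Mir6236 changed sign to 0.0858. For lists, fry called 32 in sorted cells against bulk liver, and on the slope an estimated correlation and fry each called 0 of 33, with 3 and 6 lists at an unadjusted p under 0.05. Replicate spread at 2500, 5000, 10000 and 20000 cells was 0.182, 0.138, 0.126 and 0.125 over genes of at least 1 CPM, 0.0960, 0.0698, 0.0700 and 0.0711 over genes of at least 100 CPM, and 0.210, 0.158, 0.149 and 0.147 on the deposited scores. With a pseudocount of 5 it was 0.130 and 0.0973 at 2500 and 5000 cells, and with equal totals 0.114 at 5000 cells. For detected genes r was 0.194 with at least 5 counts, 0.372 without thinning and 0.255 with TPM above 1. Leaving out 1 library at a time gave 6245 to 6934 genes higher and 5692 to 6305 lower in sorted cells, 0 to 10 on the slope, 20 to 104 for any difference, 19 to 67, 6 to 29 and 7 to 114 for 2500, 5000 and 10000 cells, 20 to 21 lists against bulk liver and 5 to 12 on the slope. The spread was then 0.105 to 0.126, 0.0833 to 0.0874, 0.0702 to 0.0893 and 0.0628 to 0.0996. These spreads rest on pairs of libraries and are not directly comparable with those of full groups. In the same repeats r was 0.806 to 0.929 for detected genes and -0.633 to -0.309 for the hepatocyte share. Of named genes that passed, 11 of 85 changed their call or sign in at least 1 alternative for sorted cells against bulk liver, 7 of 7 on the slope, and 14 of 21, 8 of 10 and 7 of 12 for 2500, 5000 and 10000 cells. The count for 2500 cells includes the contrast with the mean of 5000 and 10000 cells, which leaves out 20000 cells and is another comparison.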

Other observations

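The tests for the Kupffer cell list, for carried-over liver RNA and a steady rise of Lars2, and for the sampling and source of Jchain were chosen after the results were seen. The 12 sorted libraries were split in 100 ways into 4 groups of 3, the real one included. At least the 12 genes of the slope were given by 3 splits, with 21 and 50 genes in the others. At least the 44 genes of any difference were given by 1 split, the real one, with 34 as the highest other. Both shares are under 0.05, but they treat the libraries as independent, which the labels do not state. Since other splits exceeded the slope count, its share does not exclude chance. The split that called 50 genes may point to a structure of the samples, but what separates the libraries in it was not tested. For 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real and highest other counts were 62 and 4 for 2500 cells, 13 and 0 for 5000 cells and 45 and 1 for 10000 cells, and 1 of 10 splits, the real one, reached the real count in each.

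The Kupffer cell list lagged behind the pan-leukocyte list in sorted cells, with 12 of 14 members lower with TMM but 7 higher and none lower with library totals. The scaling thus decides the direction of the members, and with library totals the list's median was 0.33. Since it moves all genes alike, it cannot test the lag. Of the members 12 of 14 lay within 1 log2 unit of their median. As many did in 0.160% of 10000 random lists of matched bulk level, so the members did not scatter like unrelated genes. That cannot decide whether transcripts of other liver cells were counted in bulk liver, since genes of a shared other source can lie as close. The cytochrome P450 genes, for example, ran only from -11.26 to -9.24. Loss of Kupffer cells or of their RNA before or during sorting may be a cause and stays open, with the list 6.43 log2 units below the pan-leukocyte median (difference -6.43), because no value per cell exists, and no biological explanation was tested.

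Lars2 and Mir6236 were highest at 20000 cells of the 4 inputs, as were Gm15564 (947 CPM on library totals against 353 to 478) and Gm23935 (2521 against 586 to 1068), both named after their values were seen, while CT010467.1, Gm42418 and Gm26917 did not pass. Carried-over liver RNA would need a share of 28.1% and bring Alb to 5894 CPM on library totals, while Alb stood at 40.6 ± 5.10 CPM. At equal library totals the Lars2 difference between 5000 and 20000 cells was -1.59 (SE 0.08). Random thinning keeps each gene's expected share of counts, so this value cannot test whether depth accounts for the difference. A steady rise with each doubling is excluded, since the difference between 5000 and 2500 cells was -0.01745 (SE 0.08). Between 20000 and 2500 cells it was 1.57. The cause stays open, and no biological explanation was tested. In bulk liver Lars2 stood at 11920 CPM and Mir6236 at 2608 CPM on library totals, above every sorted group. Sequence reads were not analysed, so it is not known whether the counts of these features come from their own transcripts.

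Jchain was near 0 in all 3 libraries of 2500 cells. Loss of transcripts of this level at low input is argued against, since 1 of 3660 genes with 40 to 120 CPM at higher inputs fell below 1 CPM, which is 0.0273% and is Jchain itself. For random sampling of rare plasma cells, the Poisson probability of no expressing cell in the 3 samples of 2500 cells was computed. It was 6.87e-08 at the estimated rate, with 455 cells per expressing cell. At the lowest rate of the interval, with 2200 cells per expressing cell, it was 0.0333, which is near the threshold. Both values assume that each expressing cell contributes equally. A separate source of the 2500-cell samples may be a cause and cannot be told apart from cell number, with a mean of 0.349 CPM at 2500 cells, because no label names the animal or biopsy. No biological explanation was tested.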
